A study of Homo sapiens with 6 samples.

How the data were processed

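RNA was extracted from AC16 monolayers, and unstranded, poly(A)-selected libraries were made with a TruSeq kit, per the labels' protocols. The authors deposited 1 table of counts, whole-number counts per gene for 58299 Ensembl genes in 6 libraries, with gene coordinates and lengths, per the file header. The submitters' processing notes name STAR, SAMtools, Subread, featureCounts and the hg38 (GRCh38) build, without versions. The annotation release and the counting options were not given in the sources used here. Of the Ensembl identifiers, 58179 were found in GENCODE v29, 57438 with identical start and end, and 57717 had a symbol. The table holds 0 genes of the mitochondrial chromosome and has 22294 genes with 0 counts in all libraries. A library without strand information gives no way to separate a gene from an antisense or overlapping partner, and whether reads in overlapping exons or with several positions were counted is not given in the sources used here.

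The 6 libraries fall into 3 controls (0.1% DMSO for 72 h) and 3 treated libraries (100 nM CDDO-Me for 24 h, then 100 nM doxorubicin for 48 h), grouped by the treatment label. Depth was 17150259 to 20193957 counts per library. Replicates differed by more than sampling noise: a chi-square of the counts over its degrees of freedom was 3.00 to 4.01 in the 6 replicate pairs, so none was treated as a library deposited more than once. With this depth and spread, data were simulated from these libraries for the comparison of treated with control cells (15575 genes). There edgeR called 84.9% of 93 genes changed 2-fold and 72.6% of 95 changed 1.41-fold, with 5.13% of calls false. Only these genes, drawn from those above a minimum count, were changed, up or down. All simulated libraries were built on control means. In the real data 63.5% of tested genes were called, so these shares need not hold there.

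Genes were filtered with filterByExpr (minimum count 10, by group), which left 15575, and normalised by TMM. The group difference was tested with edgeR 4.0.16 (glmQLFit and glmQLFTest; R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fitted log2 changes use edgeR's prior count of 0.125. The standard error is the size of the log2 change divided by the square root of the quasi-likelihood F. For genes with 0 to 3 counts in a group, the ratio of summed counts is given with an exact 95% binomial interval. Against a group at 0, it is given against a floor of 3 counts over that group, with the lower limit of the interval. The ratio against the floor takes the count of the other group as exact, so the lower limit can lie below it. Of 21 gene lists fixed before the data were examined, 20 had at least 5 tested members and entered camera (limma 3.58.1; preset inter-gene correlation 0.01), adjusted over the lists. Exon overlap was computed with bedtools 2.31.1 from the table's own exon coordinates. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

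Genes were named by a rule fixed before the data were examined. It took the 10 protein-coding genes with the largest increase and the 10 with the largest decrease among those called, with a mean of at least 5 CPM and groups that do not overlap. It then took the 3 members of each list with the largest change, and a fixed set of genes of the NRF2, p53, cell cycle, inflammatory and heart programmes. The results of some genes that the rule took are not reported here and are left out of the counts of named genes. Members that moved against the rest of their list, further members of the BCL2, iron, stress response and cardiomyocyte lists, and genes named in the closing section were chosen after their values were seen.

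The alternatives were RLE, upper-quartile and total-count scaling, no filter or at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, a block for the replicate number, each library left out in turn, an adjusted p of 0.01, glmTreat against 1.5-fold, camera with an estimated correlation, and fry. Chosen after seeing the data were a count without genes with most of their exon bases (over 50%) in exons of another gene, and the NRF2 list without members of other lists. The tests of explanations thinned counts by sampling without replacement, resampled genes for a bootstrap interval, and regressed log2 changes on gene properties.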

Results

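Gene expression was measured by RNA sequencing in AC16 cells, a human ventricular cardiomyocyte line made by fusing adult heart muscle cells with transformed fibroblasts. Polyadenylated RNA was sequenced in 6 libraries: 3 came from cells kept in 0.1% DMSO for 72 h and 3 from cells given 100 nM CDDO-Me and 100 nM doxorubicin. CDDO-Me (bardoxolone methyl) is a synthetic triterpenoid that modifies KEAP1 and thereby releases the transcription factor NRF2, which NFE2L2 encodes. Doxorubicin is an anthracycline that traps topoisomerase II on DNA. In the labels' protocol the cells had CDDO-Me for 24 h before doxorubicin was given for 48 h, so that both groups were harvested at 72 h. The labels do not make clear whether CDDO-Me stayed on the cells with doxorubicin. The control libraries held 18323161, 17150259 and 19387496 counts in genes and the treated libraries 19792752, 19732013 and 20193957. Nothing in the labels says that replicates were separate cultures or days, so p-values measure the spread between these libraries, which may be technical.

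The series' title names NRF2 activation by CDDO-Me and doxorubicin toxicity, and the labels define 1 comparison, the combined treatment against DMSO. Cells given only one of the drugs were not analysed here, so no change below can be assigned to either drug. Levels are TMM-normalised CPM values, given as the mean ± SD of n = 3 libraries, and log2 changes are treated minus control with their standard error (SE).

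Most of the tested genes were called changed, the larger part of them by less than 2-fold. Genes of the p53 response, NRF2 targets and inflammatory factors rose, while genes of mitosis, cholesterol synthesis and the extracellular matrix fell. Of 15575 genes tested with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05, 9893 changed, 5028 higher and 4865 lower. Of these, 2410 changed at least 2-fold, 1690 higher and 720 lower, and beyond 4-fold the counts were 673 higher and 87 lower. Tested against a 1.5-fold change with glmTreat instead of against no change, 2993 of the 15575 genes were called. The groups did not overlap in 66.7% of tested genes, where chance gives 10%. The first principal component, 82.5% of the variance, separated the treated from the control libraries, and the common biological coefficient of variation was 4.82%. Higher genes made up 50.8% of the calls with TMM and 63.8% when libraries were scaled by total counts only, a scaling that moved the median log2 change of all genes from 0.02 to 0.15. All directions below are relative to the TMM median. Long non-coding genes were more often higher (439 of 1628 tested) than lower (185), while protein-coding genes were called 4409 times higher and 4559 times lower of 13056.

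**Figure D1:**
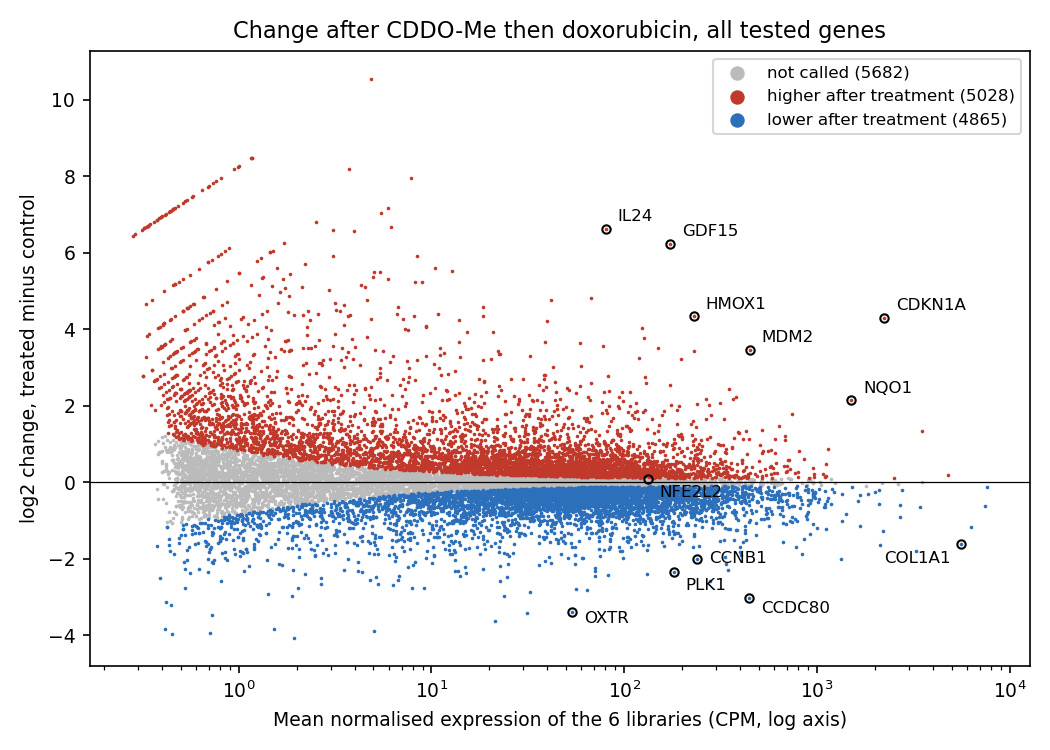
Each point is 1 of the 15575 tested genes, with the mean of the 6 libraries in CPM on a log axis and the log2 change, treated minus control, on the vertical axis. Red marks the 5028 genes called higher, blue the 4865 called lower, and the circles mark genes named in the text; the straight streaks at low expression come from genes with few counts in the controls.

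Among protein-coding genes of at least 5 CPM on average, PADI4, a peptidyl-arginine deiminase, had the largest increase, with 3 counts in the 3 controls together and 977 in the treated libraries, a ratio of 274 with a 95% counting interval of 93.5 to 1332. SULF2, a heparan sulfate sulfatase, rose from 0.0722 ± 0.13 to 11.9 ± 0.52 CPM. IL1RL1, the receptor of interleukin-33, rose from 0.0755 ± 0.088 to 10.8 ± 1.43 CPM. IL24, a cytokine, rose from 1.6 ± 0.24 to 159.2 ± 7.70 CPM, a log2 change of 6.63 (SE 0.098). GDF15, a stress-induced secreted factor, rose from 4.60 ± 1.00 to 341 ± 4.80 CPM, a log2 change of 6.22 (SE 0.079). The other genes among the 10 with the largest increases were PTPRU (log2 change 5.92), NTN1 (5.59), the decoy receptor gene TNFRSF10C (5.53), CES3 (5.51) and the riboflavin transporter gene SLC52A1 (5.49). TNFRSF10C shared 39.3% of its exon bases with exons of other genes, and the libraries carried no strand information, so its reads cannot all be told from those of its neighbours. The folds of genes with a few control counts depend on those counts: the log2 change of SULF2 was 7.17, and 10.8 without control replicate 3, which held all 4 control counts, and the log2 change of IL1RL1 was 7.03, and 8.27 without control replicate 1.

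The largest decreases among such genes were in ATOH8, a transcription factor (39.5 ± 5.14 to 3.19 ± 0.50 CPM, log2 change -3.62, SE 0.12), and COL11A1, a fibrillar collagen (log2 change -3.42). OXTR, the oxytocin receptor, fell from 98.4 ± 3.93 to 9.35 ± 0.59 CPM (log2 change -3.40). CCDC80, a matrix-associated protein, fell from 794 ± 25.6 to 97.0 ± 6.15 CPM (log2 change -3.03). CD248 (-2.98), OLFML2B (-2.87), CCBE1 (-2.82), NRP2 (-2.79), COLEC12 (-2.77) and RIPOR2 (-2.77 on the log2 scale) followed. The edgeR adjusted p of these 20 genes lay between 1.00e-58 for GDF15 and 3.66e-24 for COLEC12. Of 93 genes named by the rule fixed before the data were examined and reported here, many of them taken by it for the size of their change, 90 were tested and 87 changed, 59 higher and 28 lower.

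Of the 20 gene lists tested with camera, a competitive test of a list against the other tested genes, 8 were called higher and 3 lower. With an inter-gene correlation estimated from the data in place of the preset 0.01, 8 of the 11 calls held, and the other 3 are named with their p below. Counts of list members adjusted over the list alone equalled those adjusted over all genes tested, except for DNA replication, homologous recombination and interferon-stimulated genes, where both are given.

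**Figure D2:**
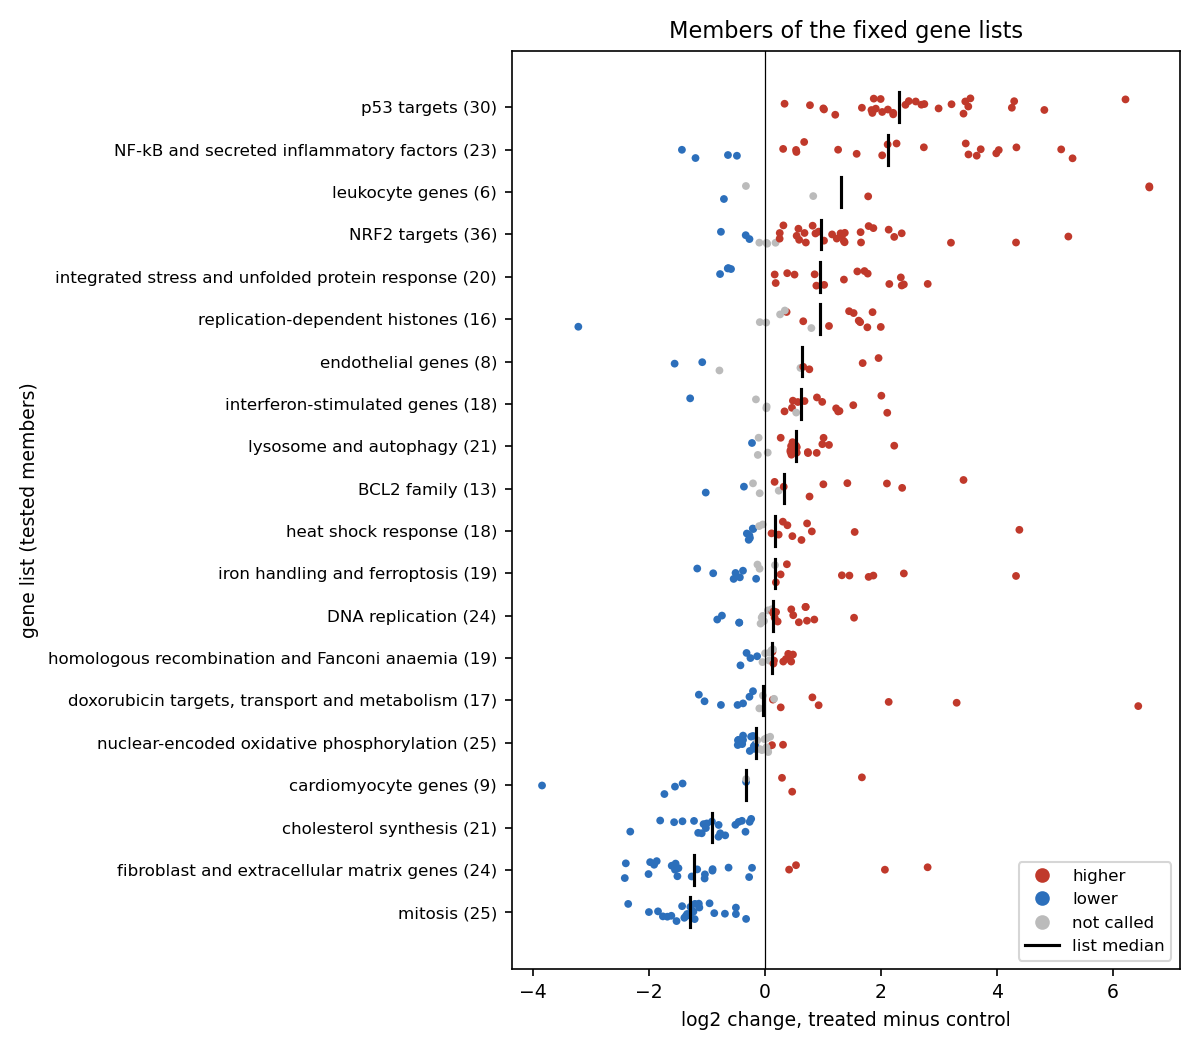
Each point is a tested member of a gene list, placed by its log2 change, treated minus control; red marks members called higher, blue members called lower, grey members not called, and black bars the list medians. The p53 list had the highest median (2.32) and the mitosis list the lowest (-1.29); with total-count scaling the medians were 2.45 and -1.16.

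NRF2 targets rose together. Of 36 tested, 29 were higher, 18 of them at least 2-fold, and 3 lower, with a median log2 change of 0.97 (camera adjusted p = 5.94e-27; adjusted p = 0.0116 with an estimated correlation). HMOX1, heme oxygenase 1 (ENSG00000100292, GRCh38 chromosome 22, 35380361 to 35394214), rose from 21.7 ± 1.31 to 437 ± 18.3 CPM, a log2 change of 4.33 (SE 0.060). NQO1, a quinone reductase (ENSG00000181019, chromosome 16, 69706996 to 69726951), rose from 561 ± 18 to 2464 ± 39.1 CPM, a log2 change of 2.13 (SE 0.046). The aldo-keto reductase gene AKR1B10 (log2 change 5.24, SE 0.22) and OSGIN1 (3.21, SE 0.11), with HMOX1, had the largest changes of the list. Genes of glutathione supply also rose: the cystine transporter gene SLC7A11 by 1.87 (SE 0.058), GCLM by 1.24 (SE 0.049) and GCLC by 1.02 (SE 0.062) on the log2 scale. TXNRD1, thioredoxin reductase, rose by 0.87 (SE 0.044) and SRXN1, sulfiredoxin, by 1.30 (SE 0.15). The 3 members that fell were the carbonyl reductase gene CBR3 (log2 change -0.76), malic enzyme ME1 (-0.33) and AKR1C3 (-0.27). Without the 10 members that also stand in other lists, a choice made after seeing the data, 22 of 26 were higher and 1 lower (camera adjusted p = 2.04e-14). The median log2 change was then 0.85. CBR3 and AKR1C3, which fell, were among the members removed, so the smaller count of falling genes comes from the removal itself.

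The transcripts of the regulators themselves moved little. NFE2L2 (ENSG00000116044, chromosome 2, 177227595 to 177392697) stood at 129 ± 1.24 CPM in controls and 136 ± 2.74 in treated cells, a log2 change of 0.07 (SE 0.050) that was not called (edgeR adjusted p = 0.231). It was called with upper-quartile factors (0.12, edgeR adjusted p = 0.0302) and with total counts only (0.20, edgeR adjusted p = 4.78e-04). KEAP1 had a log2 change of -0.09 (SE 0.055), not called (edgeR adjusted p = 0.150), and called without control replicate 3 (-0.14, edgeR adjusted p = 0.0437). Reads of members with near-identical copies, such as AKR1C1, AKR1C2 and AKR1C3, AKR1B10, TRIM16 and TRIM16L, or FTH1 and FTL with their pseudogenes, could be split between copies. SRXN1 shared 85.0% of its exon bases with exons of another gene and FTH1 62.4%.

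All 30 p53 targets rose, 28 of them at least 2-fold, with a median log2 change of 2.32 (camera adjusted p = 7.85e-115; adjusted p = 0.00266 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21 (ENSG00000124762, chromosome 6, 36676460 to 36687339), rose from 216 ± 10.7 to 4248 ± 234 CPM, a log2 change of 4.30 (SE 0.053). Besides GDF15, the anti-proliferative gene BTG2 rose from 4.59 ± 0.77 to 131 ± 4.36 CPM (log2 change 4.82, SE 0.086). MDM2, whose product degrades p53, rose from 74.9 ± 4.16 to 823 ± 40.4 CPM (log2 change 3.46, SE 0.053). BAX, a pro-apoptotic gene, rose by 1.01 (SE 0.051) on the log2 scale.

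**Figure D3:**
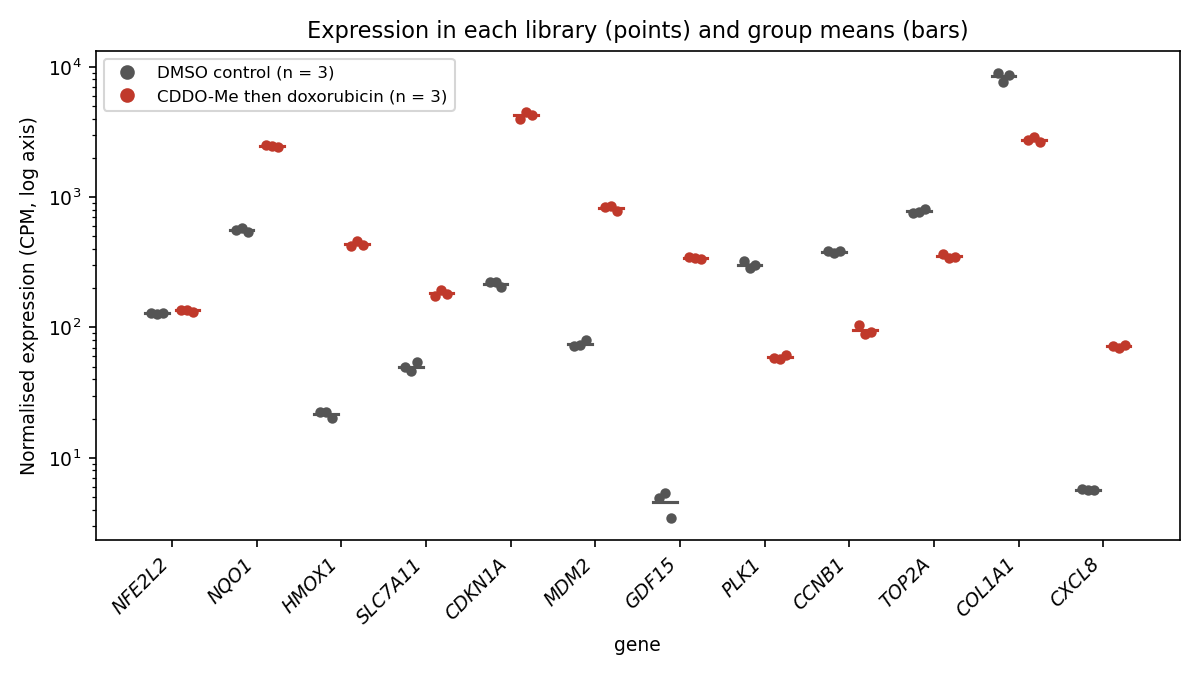
Points are the TMM-normalised expression of 12 named genes in each of the 6 libraries, in CPM on a log axis, with controls in grey and treated libraries in red; bars are the means of n = 3. CDKN1A stood at 216 CPM in controls and 4248 CPM in treated cells, while NFE2L2 stood at 129 and 136 CPM.

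In the BCL2 family, which sets the threshold of mitochondrial apoptosis, 8 of 13 tested members were higher, 2 lower and 3 not called, with a median log2 change of 0.32 (camera adjusted p = 5.44e-05, but adjusted p = 0.128 with an estimated correlation). The pro-apoptotic members BBC3 (PUMA; 3.78 ± 0.21 to 40.7 ± 0.71 CPM, log2 change 3.43), PMAIP1 (NOXA; 2.37) and BCL2L11 (BIM; 2.10) rose most. The anti-apoptotic BCL2L1 rose by 1.42 and MCL1 by 0.17, BCL2 was not called (0.24), and the pro-apoptotic BOK (-1.02) and the anti-apoptotic BCL2L2 (-0.36) fell. BCL2L1 shared 43.0% of its exon bases with exons of other genes. BAX and BBC3 also stand in the p53 list.

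All 25 mitosis genes fell, 19 of them at least 2-fold, with a median log2 change of -1.29 (camera adjusted p = 5.27e-40; adjusted p = 0.00621 with an estimated correlation). The mitotic kinase gene PLK1 fell from 304 ± 19.8 to 59.1 ± 2.42 CPM (log2 change -2.36, SE 0.054). CCNB1, cyclin B1, fell from 383 ± 7.83 to 95.4 ± 8.01 CPM (-2.0, SE 0.052), and CENPA, the centromeric histone, from 37.5 ± 4.93 to 10.4 ± 0.68 CPM (-1.85, SE 0.096). TOP2A, the topoisomerase II isoform of dividing cells and a doxorubicin target, fell from 777 ± 24.6 to 352 ± 10.9 CPM (-1.14, SE 0.046). MKI67, a proliferation marker, fell less, from 519 ± 57.8 to 366 ± 11.3 CPM (-0.50, SE 0.051).

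DNA replication genes were not called as a list. Of 24 tested, 14 were higher, 4 lower and 6 not called, and adjusted over the list alone 15 were higher and 4 lower; the median log2 change was 0.15 (camera adjusted p = 0.136). The G1/S cyclin gene CCNE1 (4.34 ± 0.33 to 12.6 ± 2.83 CPM, log2 change 1.54) and the sliding clamp gene PCNA (411 ± 15.5 to 741 ± 12.1 CPM, log2 change 0.85) rose. GINS2 (-0.82), MCM6 (-0.74), POLA1 (-0.45) and MCM5 (-0.44) fell. MCM2, a subunit of the replicative helicase, had a log2 change of -0.08 (SE 0.047), not called (edgeR adjusted p = 0.149), and called without control replicate 3 (-0.12, edgeR adjusted p = 0.0395). Among genes of homologous recombination and the Fanconi anaemia pathway, 9 of 19 were higher and 4 lower, or 10 and 4 adjusted over the list alone, and 13 and 2 with total-count scaling, with a median of 0.13, or 0.26 with total-count scaling (camera adjusted p = 0.400). ATM (0.48), EXO1 (0.45) and XRCC2 (0.43) had the largest log2 changes there.

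Replication-dependent histone genes, whose main transcripts lack a poly(A) tail and are poorly captured by poly(A) selection, were higher in 10 of 16 tested members and lower in 1, with a median log2 change of 0.95 (camera adjusted p = 0.0519). H4C8 (2.93 ± 1.02 to 11.7 ± 3.21 CPM) and H2BC21 (4.71 ± 0.15 to 17.1 ± 4.21 CPM) rose, and H2AC20 fell from 42 counts to 5. Camera called the list without control replicate 2 (adjusted p = 0.0401), without treated replicate 2 (adjusted p = 0.0147), with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.0296) and with the replicate block (adjusted p = 0.0353), and not with an estimated correlation (adjusted p = 0.531). Treated replicate 2 had fewer counts than the other treated libraries for H4C8 (162 against 286 and 281) and H2BC21 (249 against 417 and 399). Histone genes are near-identical copies, so reads could be split between them.

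The mixed list of NF-kB targets and secreted inflammatory factors rose. Of 23 tested, 19 were higher, 15 of them at least 2-fold, and 4 lower, with a median log2 change of 2.12 (camera adjusted p = 2.56e-12, and adjusted p = 0.00701 with an estimated correlation). NF-kB targets were not tested apart from the other members, so the call is no measure of NF-kB activity. The epidermal growth factor receptor ligand gene AREG rose from 0.288 ± 0.065 to 11.6 ± 0.63 CPM and the collagenase gene MMP1 from 0.250 ± 0.046 to 8.80 ± 1.34 CPM. CSF2, encoding the cytokine GM-CSF, had 2 counts in the controls and 56 in the treated libraries, a ratio of 23.6 with a 95% counting interval of 6.23 to 199.4. CXCL8, interleukin-8, rose from 5.68 ± 0.10 to 71.6 ± 1.94 CPM (log2 change 3.65, SE 0.088) and IL6 from 3.09 ± 0.39 to 14.9 ± 0.18 CPM (2.27, SE 0.14). Among the members that fell were the chemokine gene CCL2 (log2 change -1.43), TNFRSF9 (-1.20) and the NF-kB inhibitor gene NFKBIA (-0.64).

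Among interferon-stimulated genes 13 of 18 were higher, or 14 adjusted over the list alone, and 1 lower, with a median log2 change of 0.62 (camera adjusted p = 0.0188, but adjusted p = 0.183 with an estimated correlation). MX1 (0.830 ± 0.27 to 3.58 ± 0.84 CPM), ISG15 (17.8 ± 1.13 to 71.5 ± 6.19 CPM) and USP18 (0.558 ± 0.28 to 1.61 ± 0.26 CPM) rose most, and IFIT1 fell (log2 change -1.29).

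Genes of the integrated stress and unfolded protein responses were higher in 16 of 20 and lower in 4, with a median log2 change of 0.95 (camera adjusted p = 1.12e-11; adjusted p = 0.0333 with an estimated correlation). The transcription factor genes DDIT3 (CHOP; 9.71 ± 0.80 to 67.9 ± 4.63 CPM, log2 change 2.81) and ATF3 (25.5 ± 2.55 to 131 ± 12.6 CPM, 2.36) rose, as did CHAC1, a glutathione-degrading enzyme (2.40). The 4 that fell were PDIA4 (log2 change -0.78), CALR (-0.64), HYOU1 (-0.63) and HSPA5 (BiP; -0.59), which encode chaperones or folding enzymes of the endoplasmic reticulum, as do DNAJB9 (1.77) and SDF2L1 (0.18), which rose. DDIT3 shared 39.6% of its exon bases with exons of other genes. Heat shock genes were higher in 10 of 18 and lower in 6, with a median of 0.17 (camera adjusted p = 0.188). HSPA6 (0.226 ± 0.086 to 4.93 ± 0.56 CPM), HSPA4L (log2 change 1.55) and CRYAB (0.81) rose, and HSPD1 fell by 0.31 on the log2 scale.

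Lysosome and autophagy genes were higher in 17 of 21 and lower in 1 (LAMP2, log2 change -0.22), with a median of 0.53 (camera adjusted p = 1.29e-08, but adjusted p = 0.0952 with an estimated correlation). The autophagy receptor gene SQSTM1, also an NRF2 target, rose from 133 ± 5.70 to 625 ± 16.7 CPM (log2 change 2.23), and the cathepsin genes CTSB (1.10) and CTSL (1.01) rose. Iron handling and ferroptosis genes moved both ways, 9 of 19 higher and 7 lower, with a median of 0.17 (camera adjusted p = 3.16e-05; adjusted p = 0.0333 with an estimated correlation). Those that rose most, HMOX1, CHAC1 and SLC7A11, also stand in the NRF2 or stress lists, as do the ferritin genes FTH1 (1.79) and FTL (1.33). Among those that fell were the ferrireductase gene STEAP3 (-1.17), the lipid ligase gene ACSL4 (-0.89), the transferrin receptor gene TFRC (-0.51) and GPX4 (-0.38), which reduces lipid peroxides.

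All 21 genes of cholesterol synthesis and uptake fell, 10 of them at least 2-fold, with a median log2 change of -0.92 (camera adjusted p = 5.16e-19; adjusted p = 0.00701 with an estimated correlation); with total-count scaling 20 fell. DHCR7, the last enzyme of the pathway, fell from 148 ± 8.77 to 42.3 ± 1.69 CPM (log2 change -1.81).

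Fibroblast and extracellular matrix genes were lower in 20 of 24, 15 of them at least 2-fold, with a median log2 change of -1.22 (camera adjusted p = 5.94e-24; adjusted p = 0.0114 with an estimated correlation). COL1A1 (ENSG00000108821, chromosome 17, 50183289 to 50201632) fell from 8438 ± 670 to 2764 ± 104 CPM (-1.61, SE 0.048). The growth factor receptor gene PDGFRB (-2.42) and the smooth muscle gene TAGLN (-2.40) fell most. The 4 members that rose were ACTA2, smooth muscle actin (9.61 ± 0.62 to 67.4 ± 2.33 CPM, log2 change 2.81), the transcription factor gene TCF21 (2.07), FBLN1 (0.54) and COL6A1 (0.42). ACTA2 shared 30.1% of its exon bases with exons of other genes. Its span overlaps that of FAS, a p53 target on the other strand that rose from 501 to 4750 counts. The libraries carried no strand information, so reads of ACTA2 cannot all be told from those of its neighbours. How much of its rise came from them was not tested.

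Most cardiomyocyte genes had few or no counts in either group: 9 of 28 could be tested, 3 higher and 5 lower, with a median log2 change of -0.33 (camera adjusted p = 0.107). NPPB, a natriuretic peptide gene, had 41 counts in the controls and 3 in the treated libraries, all 3 in treated replicate 1, a ratio of 16.2 with a 95% counting interval of 5.18 to 82.0. PLN, RYR2 and ACTN2 went the other way, but had too few counts to be among the 9 tested and were picked after their values were seen. They had 0 counts in the controls and 30, 29 and 18 in the treated libraries. That is 8.42-fold, 8.14-fold and 5.05-fold against a floor of 3 counts over the control group, with exact 95% lower limits of 6.43, 6.21 and 3.70. Their rises were not set against the wider rise of genes with few counts, described below. DES, desmin, fell from 3.67 ± 0.71 to 1.09 ± 0.40 CPM, and MEF2C rose from 0.320 ± 0.15 to 1.05 ± 0.49 CPM. Genes of the list that other cells also express were more abundant: the calcium pump gene ATP2A2 rose from 627 ± 32.0 to 768 ± 26.2 CPM and the gap junction gene GJA1 fell from 285 ± 17.6 to 106 ± 5.76 CPM. TNNT2, cardiac troponin T, had 4 and 6 counts, and NPPA 12 and 14, too few to test. Nuclear-encoded oxidative phosphorylation genes were lower in 12 of 25 and higher in 2, with a median of -0.16 (camera adjusted p = 0.177), and with total-count scaling 8 were higher and 8 lower. COX5B (-0.47), ATP5MC1 (-0.47) and NDUFA4 (-0.46) had the largest changes. The table held no genes of the mitochondrial chromosome, so mitochondrially encoded transcripts such as MT-CO1 were not measured here.

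Genes of doxorubicin targets, transport and metabolism moved both ways, 7 of 17 higher and 7 lower (camera adjusted p = 0.410). The list's median log2 change was -0.04, or 0.02 and 0.09 with upper-quartile and total-count scaling, while its mean was 0.58 and the test pointed up. That mean leans on the fitted log2 change of ABCB1, 6.44, which depends on edgeR's prior count. ABCB1, the efflux pump P-glycoprotein, had 0 counts in all 3 controls and 35 in the treated libraries. That is 9.82-fold against a floor of 3 counts over the control group, with an exact 95% lower limit of 7.57. XDH, xanthine oxidoreductase, rose from 1.74 ± 0.52 to 17.1 ± 0.28 CPM. TOP2B, the other topoisomerase II isoform, fell from 123 ± 8.66 to 94.4 ± 8.47 CPM (log2 change -0.38, SE 0.057).

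Markers of cell types not named in the labels were mostly low, with the exception of ENG, endoglin, which fell from 214 ± 23.2 to 101 ± 0.49 CPM (log2 change -1.08). Of 8 endothelial genes tested, 4 were higher and 2 lower (camera adjusted p = 0.410); the median log2 change was 0.64 and the mean 0.28, but the test pointed down. PECAM1 (0.369 ± 0.38 to 1.49 ± 0.39 CPM) and CLDN5 (0.302 ± 0.17 to 0.993 ± 0.27 CPM) rose, and TEK fell from 20.7 ± 0.63 to 7.01 ± 0.48 CPM. The log2 change of PECAM1 was 1.96, and 3.28 without control replicate 3, which held 15 of its 20 control counts. Of 6 leukocyte genes tested, 3 were higher and 1 lower (3 and 0 with total-count or upper-quartile scaling), with a median of 1.31 (camera adjusted p = 0.400). LYZ and ITGAM each had 0 counts in the controls and 40 in the treated libraries. That is 11.2-fold against a floor of 3 counts over the control group, with an exact 95% lower limit of 8.71. PTPRC rose from 1.11 ± 0.17 to 3.82 ± 0.45 CPM. Counting intervals, limits and floors cover counting error only, and floors only that of the group with 0 counts. They do not cover a wider rise of genes with few counts. Genes with any count numbered 21816 to 22205 in control libraries and 28021 to 28482 in treated ones, before depth was equalised. Rises from 0 control counts were not set against that background.

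More genes were detected after treatment. At least 10 counts were reached by 14627 ± 126 genes in the controls and 16216 ± 165 in the treated libraries, and thinned to an equal 17150259 counts per library by 14484 ± 34.2 and 15763 ± 124 genes. The 3 treated libraries lay above the 3 controls in both, for which an exact two-sided permutation test gives p = 0.1, the smallest this design allows. The 100 most abundant genes took 17.1% ± 0.26 of counts in controls and 14.8% ± 0.23 in treated libraries.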

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

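The 9893 changed genes ranged from 9244 (DESeq2) to 11032 (no filter) at the same threshold, with 9238 and 9359 of the main calls shared, and leaving out 1 library gave 9283 to 9695. An adjusted p of 0.01 left 8513, and without overlapped genes, chosen after seeing the data, 9768 changed. With the filter of at least 1 CPM in at least 3 libraries, 1895 genes changed at least 2-fold, against 2410 in the main run. Without a filter 36005 instead of 15575 genes entered, and 3994 changed at least 2-fold. The gain was mostly upward: those higher at least 2-fold went from 1690 to 3175 and those lower from 720 to 819. The median log2 change of all tested genes was then 0.51, against 0.02 in the main run. Replicate numbers did not pair the samples: same-numbered deviations correlated at -0.0225, -0.00714 and -0.00718, no treated library with its own number best, and the replicate block gave 9653 genes. Scaling by total counts turned 2 uncalled log2 changes: KEAP1 to 0.0382 and MCM2 to 0.0511. Camera with an estimated correlation ended the calls of the interferon list (adjusted p = 0.183), BCL2 family (0.128) and lysosome list (0.0952). Over the camera alternatives adjusted p ranged from 0.0116 to 0.183, 4.32e-05 to 0.128 and 4.63e-09 to 0.0952 for these lists. Fry's mixed test, a test against no change, gave adjusted p = 4.07e-05 for the interferon list and 9.41e-07 for the BCL2 family. The histone list passed camera with the stricter filter (adjusted p = 0.0296) and the replicate block (0.0353), and leaving out 1 library gave 0.0147 to 0.0817. The cause was not tested, and over the camera alternatives adjusted p ranged from 0.0147 to 0.531. Fry, which asks only whether a list's genes move, called lists that camera did not, as directional and mixed adjusted p: DNA replication 0.00416 and 4.23e-06, homologous recombination 0.0143 and 1.04e-05, histones 0.00492 and 0.00124, heat shock 0.00169 and 9.41e-07, oxidative phosphorylation 0.00215 and 1.37e-05, doxorubicin 0.00160 and 9.41e-07, cardiomyocyte 6.36e-04 and 1.24e-05, endothelial 0.0235 and 1.25e-05, leukocyte 7.34e-04 and 8.04e-06. Both fry tests called every list tested. With 63.5% of tested genes changed, a test against no change can hardly fail, so fry's calls tell no list from another. That holds also for its p-values of the interferon list and the BCL2 family. Library sizes without mitochondrial genes were not run, since the table holds none. Of the lists tested, the cardiomyocyte (9 of 28) and leukocyte (6 of 12) lists had the smallest shares of members with enough counts to test.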

Other observations

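Tests chosen only after their result was seen were those of gene families, of other splits of the libraries, of depth and of the share of cycling cells. Genes were grouped into 25 families by the start of their symbols, which can take in genes that are not family members. The tubulin group fell: 13 of 18 were lower and 0 higher with TMM (12 and 2 with total-count scaling). Its median log2 change was -0.73 (camera adjusted p = 3.61e-10, but adjusted p = 0.136 with an estimated correlation). TUBB fell from 3211 to 1019 CPM and TUBA1A had a log2 change of -1.96. Kinesins, motor proteins of which many act in the spindle, were lower in 19 of 31 and higher in 5 (16 and 8 with total-count scaling), led downward by KIF18A (-1.53), KIF23 (-1.42) and KIF14 (-1.38). Dual-specificity phosphatases, some of which switch off MAP kinases, were higher in 11 of 18 and lower in 4 (11 and 2 with total-count scaling). DUSP4 (log2 change 3.03), DUSP6 (2.70) and DUSP5 (2.08) were at the top. Genes with symbols of the vacuolar ATPase, the proton pump of lysosomes, were higher in 15 of 21 and lower in 1 (median 0.41). Camera called 11 of the 25 families, and 0 held with an estimated correlation (smallest adjusted p = 0.131).

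Collagen genes split: 15 of 34 rose and 16 fell, and the median was 0.01 although the test pointed down. The abundant fibrillar collagens COL3A1 (log2 change -2.01), COL5A2 (-1.87) and COL1A1 (-1.61) fell. COL7A1, which anchors epithelia to the matrix, rose from 51.0 to 296 CPM (2.54). The largest increases were in collagens with few control counts, COL2A1, also fibrillar (0.0191 to 1.67 CPM), COL17A1 (0.0755 to 4.34 CPM), COL9A3 (0.115 to 1.38 CPM) and COL21A1 (0.234 to 1.41 CPM). Serpins, mostly protease inhibitors, were higher in 10 of 17 and lower in 3, with SERPINB2 (3.44) and SERPINE2 (2.07) up and the collagen chaperone SERPINH1 (-1.25) down. Of 16 TNF receptor genes, 8 were higher and 7 lower (camera adjusted p = 0.0121, but adjusted p = 0.233 with an estimated correlation). TNFRSF10C (log2 change 5.53), TNFRSF14 (4.40), TNFRSF10A (2.64) and TNFRSF10B (2.42) rose most, and TNFRSF19 (-1.41), TNFRSF9 (-1.20) and TNFRSF1B (-1.17) fell most. The cholesterol exporter gene ABCA1 rose from 4.04 to 75.4 CPM (4.22).

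Mitosis genes fell while replication genes as a list did not, which may reflect an arrest that leaves replication transcripts in place. The medians of the 2 lists differed by -1.4338 in log2. A smaller share of cycling cells as the whole cause would forbid this only if it lowered both lists alike. That premise was not tested, and the difference is the pattern itself, so it does not decide the question. The lowest replication gene, GINS2 (-0.82), lay above the mitosis median of -1.29, but MKI67 (-0.50) of the mitosis list fell less than GINS2. After GC and exon length trends were removed the difference of the medians was -1.4334, which argues against those biases. Also open, and untested here, are a build-up of cells in one phase of the cycle and lower transcription of mitotic genes per cell. The 2 drugs cannot be separated in this design.

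More genes reached 10 counts after treatment. Depth cannot account for it, with a difference of 1279.3 genes at equal counts, nor can abundant genes taking more of the control counts, with 1016.3 genes at one effective library size. Genes overlapping no other gene gained 429.3 (9.87%, against 8.39% for overlapping genes), which argues against intronic reads of other genes as the whole cause. Genomic DNA falls short for the genes compared. The 381 olfactory receptor genes, silent in most cells, reached at most 0.0149971 CPM per kb (upper 95% bound, counting error only) in treated libraries. The receptors themselves went from 244 to 642 counts. The 602 genes that reached 10 counts in all treated and no control libraries gained a median of 0.294. They were selected for a gain in these libraries, and genes that crossed less consistently were not compared. A wider set of genes transcribed at low level after treatment is a hypothesis these data suggest, found and tested on the same libraries.

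Genes with a long genomic span were lower after treatment. The median log2 change was -0.14 for 2638 protein-coding genes over 100 kb and 0.06 for 4557 under 20 kb, a difference of -0.1922 (bootstrap 95% interval -0.224 to -0.160). Spearman's rho across 13056 genes, which are not independent, was -0.0994, just short of the -0.1 set in advance, so whether span itself is the cause stays undecided. GC content, exon length, the number of annotated exon entries and expression level do not carry the trend. Its coefficient per factor of 10 in span was -0.0765 alone and -0.102 with them in the regression. Exon entries count an exon once for each annotated transcript, so exon number itself was not adjusted for. Slower or blocked elongation on DNA damaged by doxorubicin is a candidate explanation that was not tested.

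Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes, the real one, with 9893 genes against 0 in the highest of the others. So few splits cannot give a share below 0.05.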
